A study of Mus musculus with 3 samples.

How the data were processed

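Lung cells of female C57BL/6 mice aged 9 weeks were profiled 24 h after intratracheal treatment. Saline was given with IgG, and E. coli either with IgG or with anti-LIF, with 1 library per group and 3 libraries in all. IgG is the control antibody and anti-LIF an antibody that blocks leukemia inhibitory factor. Per the labels, cells were sorted from lung digests and pooled before capture on the 10x Genomics platform; the gate of the sort and the number of mice per library are not stated there. The deposited values are raw UMI counts per gene and cell barcode, which the authors made with Cell Ranger 3.1.0 on mm10 per the labels, with no normalization. The annotation and the cell filter are not stated; on the values, every deposited cell had at least 500 UMIs and 300 genes. The table held 7291 cells and 19840 gene rows, of which 13 repeated a gene name and were summed, leaving 19827 names.

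Cells with at least 500 UMIs, at least 300 genes and at most 20% mitochondrial UMIs were kept, and Scrublet, as implemented in scanpy 1.11.5, was run per library. The mitochondrial limit removed 449, 114 and 204 cells of IgG saline, IgG E. coli and anti-LIF E. coli (16.2%, 6.66% and 7.27%), and called doublets 14, 6 and 43, or 0.966% of 6524 cells. Clustering used log-normalized counts, 2000 variable genes, 30 principal components, 15 nearest neighbours and Leiden resolution 1.5 without batch integration, which gave 41 clusters. Other tools were anndata 0.12.19, leidenalg 0.10.2, igraph 0.11.9, scikit-learn 1.9.0, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 under Python 3.11.15.

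Clusters were named from 325 marker genes of 25 cell classes written before the data were examined. A name needed at least 3 higher markers and no conflict with markers of another class among the cluster's top 10 genes. A cluster whose markers of a second compartment reached 50% of its best score, or that cell cycle genes led, stayed unnamed. The thresholds of this naming were set after the data were seen, because a stricter form left many cells unnamed. Named classes are written as AT2-like and so on. A class was compared between libraries when it had at least 50 cells in each, and its compartment (epithelial, endothelial, mesenchymal or hematopoietic) was computed beside it. Marker genes Acod1, Cavin2, Gucy1a1, Gucy1b1 and Mcpt8 and list genes Cebpd, Cntf, Fgb, Gsdme and Il17c had no row under those names and were not analysed here.

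Counts were summed over the cells of a class and library and scaled to a common total (CPM). Ratios are log2 of CPM plus 10 over CPM plus 10, and 2-fold on this scale marks a gene as higher or lower. Folds printed for single genes are plain CPM ratios without the added 10, so they are larger than the log2 ratio of the same gene implies. The 3 comparisons were IgG E. coli against IgG saline, anti-LIF against IgG in E. coli, and, for lists alone, anti-LIF E. coli against IgG saline. No paired analysis was possible because each group has 1 library, and no p-value was computed. Intervals are exact Poisson (counts) or exact Clopper-Pearson (shares) 95% intervals, and for list medians the 2.5 to 97.5 percentiles of 1000 Poisson resamples. They cover counting error only, not differences between mice or libraries. Those of counts, folds and list medians also leave out the spread between cells of a class. A fold against 0 counts was taken against a floor of 3 counts per class sum and is written as at least.

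The 26 gene lists (464 genes, 43 of them in 2 or more lists) were written before the data were examined: LIF axis, STAT3 targets, NF-kB targets, chemokines and colony-stimulating factors, acute phase and antimicrobial, interferon response, MHC class I, MHC class II, surfactant and AT2 lipid, AT2 transitional state, epithelial barrier and ion transport, pro-apoptotic, anti-apoptotic, p53 targets, pyroptosis and necroptosis, proliferation, glycolysis and hypoxia, unfolded protein response, dissociation and immediate-early, oxidative stress, endothelial activation, endothelial junction and identity, matrix, repair growth factors, alveolar macrophage identity, and neutrophil activation. A member counted as measured with at least 20 UMIs over the libraries compared, and a list needed 5 such members. Its median log2 ratio is given with its percentile among 10000 random lists of equal size matched on mean CPM in 20 bins. A member under 10% of its highest class in the library where it was higher was marked as open to free RNA, the RNA that leaks into droplets of other cells. Only classes of at least 20 cells in that library entered this mark. Alveolar macrophage-like and club-like cells of IgG E. coli, with 3 and 7 cells, did not. Mesothelial-like (10, 12 and 17 cells) and lymphatic endothelial-like cells (2, 5 and 6) were left out in each library. So were type 2 innate lymphoid-like cells of IgG E. coli and anti-LIF E. coli (1 and 2). Club-like cells of IgG saline (10) and dendritic-like cells of anti-LIF E. coli (14) were also left out. Free RNA from these classes could not be marked in those libraries. Where the median of all measured genes moved by more than 0.1, which it did in neutrophil-like and fibroblast-like cells after E. coli, values are given relative to it.

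Genes named in the text are those of the LIF axis list, the 6 highest and 6 lowest in AT2-like cells and the 3 highest and 3 lowest in the largest endothelial, mesenchymal, macrophage and neutrophil class, and the 2 to 4 members of each described list with the largest ratios. The ranked genes needed at least 50 UMIs and no mark of free RNA, and mitochondrial, ribosomal, hemoglobin, immunoglobulin and T-cell receptor genes and unnamed gene models were not ranked. Bst2 and Sftpd in AT2-like cells, Irf7, Ifit1 and Isg15 in general capillary-like cells, Saa1 in fibroblast-like cells with anti-LIF, and the genes followed within single clusters were chosen after their values were seen. Some genes that the rule names are not reported here.

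The procedure was tested on simulated data: class sums were drawn at the depth of these libraries with some genes set to a known ratio. Of genes set 4-fold apart, 70.0% passed 2-fold in AT2-like cells after E. coli, 63.6% with anti-LIF, and between 79.0% and 90.8% in general capillary-like and fibroblast-like cells, because the pseudocount pulls weak genes toward 0. Of genes set 2-fold apart, 0% and 2.02% passed in AT2-like cells and at most 20.4% elsewhere, so a list with no member past 2-fold can still hold differences of about that size. Counting intervals covered the true ratio for 94.97% to 97.5% of the genes set apart. The simulated sums were Poisson draws, so this coverage was built in. It does not show how the intervals hold where UMIs are spread unevenly over cells. Simulated lists of unchanged genes had medians from -0.12 to 0.03 and percentiles from 3.08 to 96.9, so a percentile between those is no more extreme than lists with no difference gave. Only a single such list was drawn per class and comparison, so this range is rough. For list medians 13 alternatives were planned: pseudocounts of 1 and 50 CPM, size factors, a minimum of 50 UMIs or none, doublets kept, a 10% mitochondrial limit, 1000 UMIs per cell, resolution 0.8, classes from marker scores, equal weight per cell, cells thinned to 1000 UMIs, and members open to free RNA left out. Alternatives on single clusters and on subsets of AT2-like, AT1-like and neutrophil-like cells were added after the values were seen.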

Results

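The data were droplet-based single-cell RNA-seq libraries of lung cells from mice killed 24 h after material was placed in the trachea. There were 3 groups with 1 library each: saline with a control antibody (IgG saline), E. coli with the control antibody (IgG E. coli), and E. coli with an antibody that blocks LIF (anti-LIF E. coli). LIF, leukemia inhibitory factor, is a cytokine of the interleukin-6 family that acts on cells through the receptor chains Lifr and Il6st. The table held 2773 cells with 25195999 UMIs for IgG saline, 1711 cells with 20155452 UMIs for IgG E. coli, and 2807 cells with 32280800 UMIs for anti-LIF E. coli. After filters, 2310, 1591 and 2560 cells were kept, with median depths of 5907, 6166 and 5519.5 UMIs per cell. With 1 library per group there is no test of any difference between groups. Intervals are 95% intervals that cover counting error only.

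Epithelial, endothelial, mesenchymal and immune classes were found in each library. Alveolar type 2 (AT2)-like cells, the surfactant-making cells of the alveolus, made up 16.4% (14.9 to 17.98%) of kept cells in IgG saline, 16.9% (15.1 to 18.8%) in IgG E. coli and 23.9% (22.3 to 25.6%) in anti-LIF E. coli. Neutrophil-like cells made up 4.33% (3.54 to 5.24%), 13.4% (11.8 to 15.2%) and 13.9% (12.6 to 15.3%). Fibroblast-like cells made up 10.5% (9.30 to 11.8%), 7.23% (6.00 to 8.61%) and 3.28% (2.63 to 4.05%), and general capillary-like endothelial cells 12.9% (11.6 to 14.3%), 16.6% (14.8 to 18.5%) and 16.7% (15.3 to 18.2%). Alveolar macrophage-like cells numbered 140, 3 and 46, and the 46 had a median depth of only 792.5 UMIs. B-like cells numbered 125, 77 and 33, and T-like cells 162, 52 and 39. Per the labels, cells were sorted and pooled before capture, so these shares carry the sort and the pooling as well as the lung. Cells in clusters left unnamed made up 7.32%, 8.30% and 12.3%.

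The first question was which cells held RNA of LIF, its receptor and its relatives. Of the classes compared after E. coli, fibroblast-like cells held the most Lif in IgG saline and IgG E. coli. They had 24.3 (17.8 to 32.4) CPM (UMIs scaled to a common class total) in IgG saline, 112 (96.1 to 131) in IgG E. coli and 11.3 (5.82 to 19.7) in anti-LIF E. coli. Type 2 innate lymphoid (ILC2)-like cells, a class with 30, 1 and 2 cells, held more in IgG saline, at 139.9 (97.4 to 195) CPM, and were too few in the E. coli libraries to give a level. In anti-LIF E. coli, Lif in AT1-like cells (13.6 (6.77 to 24.3) CPM) and monocyte- or macrophage-like cells (11.2 (6.27 to 18.5) CPM) was within counting error of the fibroblast level. Alveolar macrophage-like cells of that library had 18.6 (6.05 to 43.5) CPM, but from only 5 UMIs in 2 of 46 cells. A Lif UMI was seen in 8.23% (5.10 to 12.4%), 22.6% (15.3 to 31.3%) and 9.52% (4.20 to 17.9%) of fibroblast-like cells, at median depths of 6920, 10077 and 9534 UMIs. The Lif UMIs numbered 46, 169 and 12 in 20, 26 and 8 cells, so the CPM values rest on few cells. The share intervals of the 2 E. coli libraries overlap. With each cell thinned to 1000 UMIs the shares were 0.830%, 4.42% and 2.41%. Neutrophil-like cells gave a background of 1%, 0.939% and 0.281% at 4544, 4264 and 3698 UMIs. Il6, the founding cytokine of the family, had 52.8 (42.9 to 64.2), 433 (399.9 to 467) and 117 (97.6 to 139.7) CPM in fibroblast-like cells, and Il11 had 4.22 (1.82 to 8.32), 24.6 (17.3 to 33.9) and 1.88 (0.227 to 6.78) CPM. The Il11 values come from 8, 37 and 2 UMIs in 6, 6 and 2 cells, so they describe few cells and not the class. Within fibroblast cluster 11 alone, chosen after the values were seen, Lif stood at 3.65 against 95.8 CPM and Il6 at 81.6 against 355 CPM for anti-LIF against IgG in E. coli. Cluster 11 held few of the fibroblast-like cells of IgG saline, so differences between IgG saline and IgG E. coli carry a different mix of clusters.

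Lifr, the LIF receptor chain, was highest in endothelial classes. It had 279 (251 to 310.2) CPM in general capillary-like cells of IgG saline, 172 (150.4 to 196) in IgG E. coli and 162 (143 to 182) in anti-LIF E. coli, and 313, 158 and 225 CPM in large vessel-like cells. AT2-like cells held less, at 44.2, 26.9 and 24.1 CPM. Il6st, the signalling chain shared by the family, had 286, 162 and 195 CPM in general capillary-like cells and 139, 188 and 298 CPM in fibroblast-like cells. Osm, oncostatin M, was highest in neutrophil-like cells, with 299, 845 and 989.8 CPM, and stood at 75.5, 211 and 340.0 CPM in monocyte- or macrophage-like cells. Its receptor Osmr had 38.5, 89.2 and 56.1 CPM in AT2-like cells, and more in fibroblast-like cells, at 103, 155 and 159 CPM. Socs3, a feedback inhibitor of this pathway, had 144 (123 to 166), 117 (99.5 to 137) and 448 (417 to 482) CPM in general capillary-like cells. It is also a member of the dissociation and immediate-early list. In neutrophil-like cells Lifr stood at 4.24, 22.9 and 1.98 CPM, an order that turned when called doublets were kept. The value of 22.9 came from 25 UMIs in 11 of 213 cells. At least 3 UMIs of capillary markers were present in 3%, 13.6% and 2.25% of neutrophil-like cells of the 3 libraries in turn. Endothelial material could thus account for the Lifr values, which was not tested. Positions on mm10 are Lif on chromosome 11 from 4257557 to 4272514, Lifr on chromosome 15 from 7090614 to 7197489, Il6 on chromosome 5 from 30013114 to 30019981 and Socs3 on chromosome 11 from 117966079 to 117970047.

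**Figure D1:**
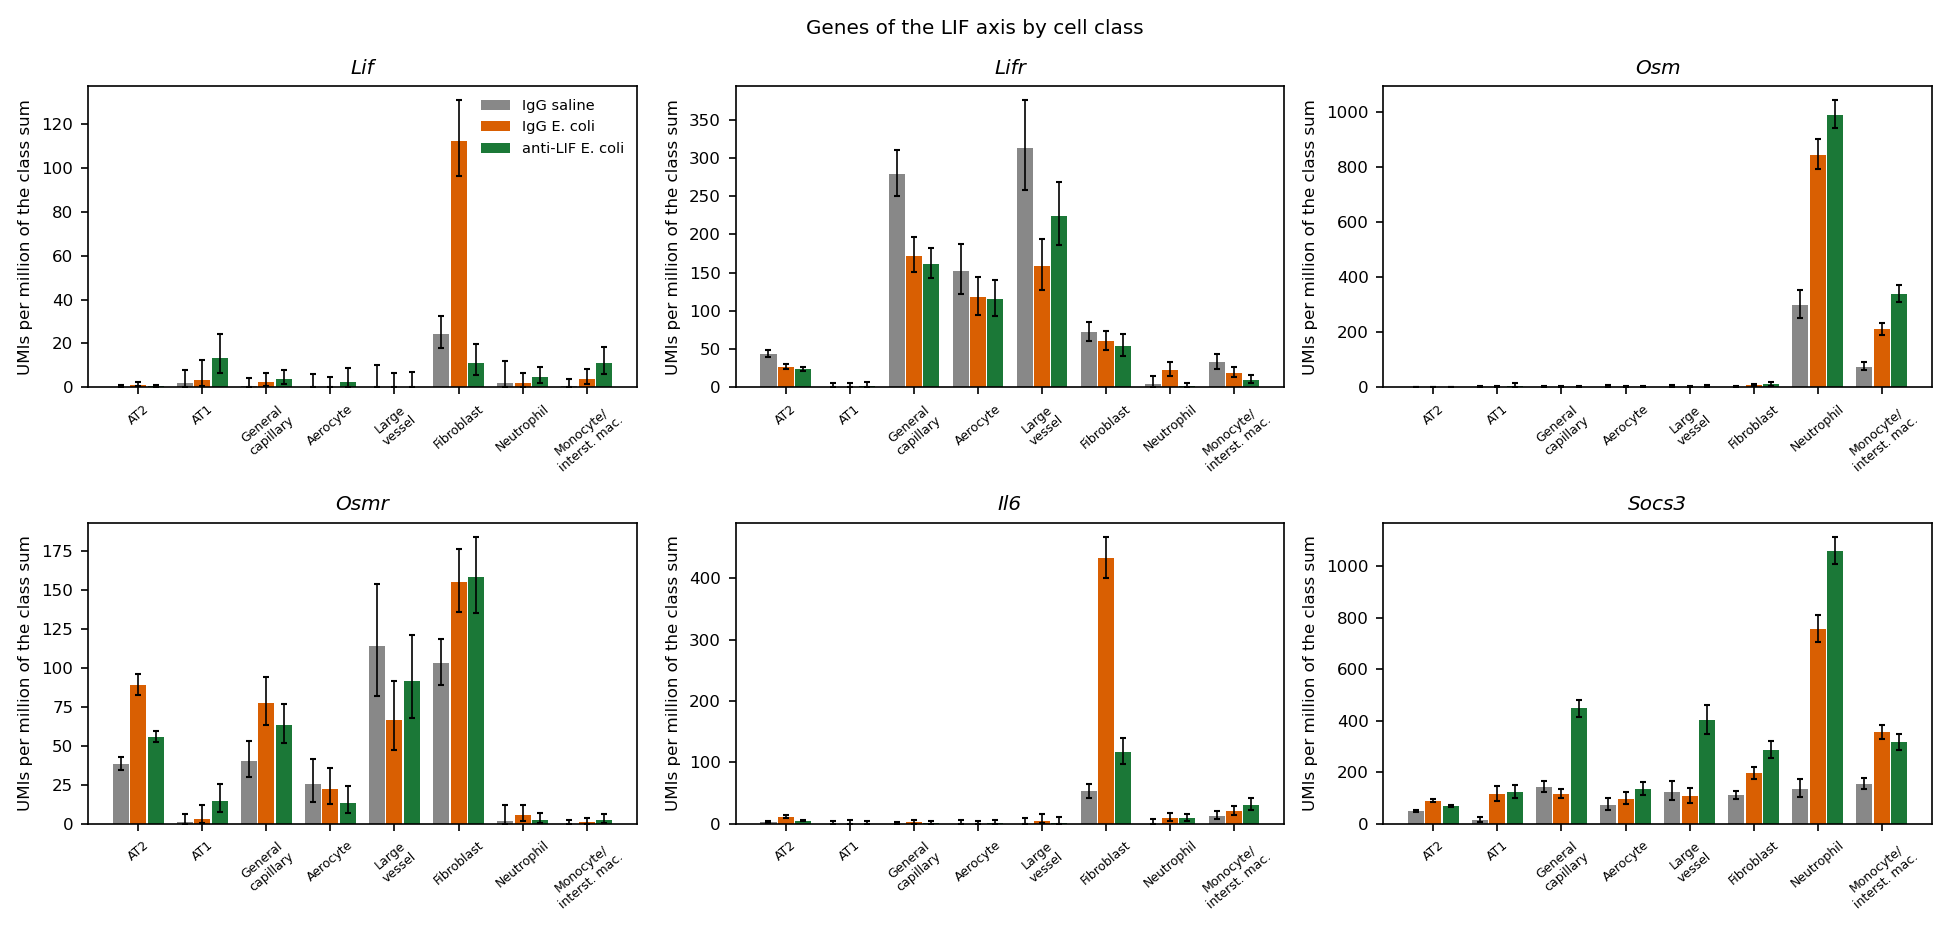
CPM of the class sum for 6 genes of the LIF axis in 8 cell classes, with a bar for each library and whiskers for 95% Poisson intervals (counting error only). Of the classes plotted, Lif and Il6 peak in fibroblast-like cells of IgG E. coli (112 and 433 CPM), Lifr in endothelial classes, and Osm in neutrophil-like cells.

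The comparison of IgG E. coli with IgG saline asked how each lung cell class differed 24 h after infection. In AT2-like cells the acute phase and antimicrobial genes stood out: Orm1, which codes for the plasma protein orosomucoid, was 175-fold higher (146 to 213), and Pglyrp1, a protein that binds bacterial peptidoglycan, was 37.2-fold higher (29.3 to 47.8). The neutrophil attractants Cxcl5 and Cxcl1 were 504-fold higher (231 to 1373) and 46.0-fold higher (37.6 to 57.0). The median log2 ratio of the interferon response list ran from 0.49 in B-like cells, where 2 of 8 measured members were at least 2-fold higher, to 2.68 with 21 of 21 in alveolar type 1 (AT1)-like cells, the flat cells of gas exchange. Fibroblast-like cells held far more Saa3, Saa1 and Lcn2, and neutrophil-like cells more Il1a, Cxcl10 and Ccl3. Below, a list median is followed by its 95% counting interval and by its percentile among 10000 random lists of the same size and expression, as a description of these libraries.

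Of the acute phase list in AT2-like cells, 11 of 14 measured members were at least 2-fold higher and 0 lower, with a median log2 ratio of 2.18 (2.15 to 2.22, percentile 100). Lcn2, which withholds iron from bacteria, had a log2 ratio of 3.58. With no minimum UMI count for a member, the median was 1.12. Of the chemokine list, 10 of 14 measured members were at least 2-fold higher and 0 lower, with a median of 1.41 (1.29 to 1.51, percentile 100), and Ccl20, a chemokine for lymphocytes and dendritic cells, had 3.55. Among NF-kB targets, 12 of 20 measured members were at least 2-fold higher and 1 lower, with a median of 1.26 (1.14 to 1.34, percentile 100). Cd83, an activation marker, had 3.36 and the mitochondrial superoxide dismutase Sod2 2.87. Of the STAT3 targets, 6 of 20 measured members were at least 2-fold higher and 0 lower, with a median of 0.55 (0.48 to 0.63, percentile 99.9), led by Hp (haptoglobin, 2.51) and Icam1 (1.61). The LIF axis list had a median of -0.05 (-0.16 to 0.10, percentile 26.3), with Osmr at 1.03 and Stat3 at -0.56.

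Of the MHC class I list in AT2-like cells, 10 of 14 measured members were at least 2-fold higher and 0 lower, with a median of 1.37 (1.29 to 1.44, percentile 100), and the immunoproteasome subunits Psmb8 and Psmb10 had log2 ratios of 2.01 and 1.85. The MHC class II list had a median of 0.98 (0.88 to 0.997, percentile 99.9), with H2-Eb1 at 1.06 and H2-Ab1 at 1.01. Of the interferon list, 14 of 21 measured members were at least 2-fold higher and 0 lower, with a median of 1.35 (1.25 to 1.51, percentile 100), but 14 members lay under 10% of their highest class and can hold free RNA. Bst2, which holds budding virus at the cell surface, was not among those and, picked for that reason, had 2.22. Other genes among the 6 highest in AT2-like cells were Il4i1, a secreted amino acid oxidase, at 99.0-fold higher (76.7 to 130.3), and Ly6i, a surface protein of the Ly6 family, at 43.0-fold higher (37.5 to 49.7).

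Of the surfactant and lipid genes of AT2-like cells, 0 of 23 measured members were at least 2-fold higher and 6 lower, with a median of -0.69 (-0.72 to -0.59, percentile 0). Sftpc, surfactant protein C, had a log2 ratio of -1.95 and the sterol synthesis gene Hmgcs1 -1.36, while Sftpd, surfactant protein D, picked as a member with the opposite sign, had 0.87. The 6 lowest genes of the class were Retnla at 37.3-fold lower (33.3 to 41.9), Bex2 at 6.61-fold lower (5.95 to 7.35), the complement gene Hc at 5.68-fold lower (5.42 to 5.95), Cst8 at 9.93-fold lower (7.70 to 12.98), Acoxl at 5.54-fold lower (5.02 to 6.12) and the circadian repressor Nr1d1 at 9.14-fold lower (6.71 to 12.7). Most AT2-like cells of IgG saline lay in cluster 2, led by Hc, Acoxl and Bex2. Most of both E. coli libraries lay in cluster 0, led by Orm1 and Lcn2, and cluster 3, led by Cxcl5 and Ccl20.

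The remaining lists in AT2-like cells had smaller medians. Of the unfolded protein response list, 8 of 19 measured members were at least 2-fold higher and 0 lower, with a median of 0.60 (0.56 to 0.76, percentile 99.9) and Sdf2l1 and Manf at 1.93 and 1.53. The transitional state list had 5 higher and 1 lower of 18 members and a median of 0.55 (0.47 to 0.60, percentile 99.95), with Tnip3 at 3.25 and the secreted chaperone Clu at 1.80. Medians were 0.44 (0.35 to 0.53, percentile 99.8) for glycolysis, with Eno1 at 1.54, and 0.39 (0.34 to 0.49, percentile 99.9) for pyroptosis and necroptosis, with Zbp1 at 1.94. They were 0.36 (0.27 to 0.45, percentile 99.5) for proliferation, with H2afz at 2.04 and Stmn1 at -1.02, and 0.28 (0.23 to 0.37, percentile 84.0) for oxidative stress, with Mt2, a metallothionein, at 1.28. Pro-apoptotic genes had a median of 0.26 (0.19 to 0.34, percentile 99.8), with Bax at 1.10, and anti-apoptotic genes -0.05 (-0.13 to 0.06, percentile 20.9), with Birc3 at 1.32. p53 targets had 0.21 (0.02 to 0.34, percentile 96.3), barrier and ion transport genes -0.07 (-0.11 to 0.02, percentile 6.78) with no member past 2-fold, and repair growth factors -0.22 (-0.41 to -0.14, percentile 2.44), with Bmp4 at -0.64. Of the dissociation and immediate-early list, 1 of 20 measured members were at least 2-fold higher and 6 lower, with a median of -0.53 (-0.58 to -0.48, percentile 0) and Dusp1, a phosphatase of MAP kinases, at -1.74.

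In AT1-like cells, 21 of 21 interferon response members were at least 2-fold higher, with a median of 2.68 (2.46 to 2.92, percentile 100). Iigp1, a GTPase that acts on pathogen vacuoles, had a log2 ratio of 4.38 and Irf7, a transcription factor of the interferon response, 4.35. The MHC class I list had 12 of 12 members higher and a median of 1.85 (1.71 to 1.94, percentile 100). Medians were 0.30 (0.01 to 0.65, percentile 96.8) for STAT3 targets, with Socs3 at 2.31 and Myc at 2.30, -0.11 (-0.33 to 0.08, percentile 38.2) for NF-kB targets, 0.53 (0.06 to 0.85, percentile 99.3) for chemokines, 0.22 (-0.10 to 0.43, percentile 96.7) for pro-apoptotic genes and 0.01 (-0.11 to 0.26, percentile 57.1) for immediate-early genes.

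Interferon response genes were the most uniform difference in general capillary-like endothelial cells: 23 of 24 measured members were at least 2-fold higher and 0 lower, with a median of 1.98 (1.86 to 2.18, percentile 100). Iigp1 was 13.3-fold higher (10.5 to 17.0), the antiviral gene Ifit3 had a log2 ratio of 3.33 and the GTPase Igtp 3.09. Of the MHC class II list, 7 of 8 measured members were at least 2-fold higher and 0 lower, with a median of 2.17 (2.01 to 2.32, percentile 100), including the peptide loader H2-DMb1 (2.49) and H2-Ab1 (2.24). The MHC class I list had a median of 1.02 (0.94 to 1.10, percentile 100), led by the peptide transporter Tap1 (2.20). The T-cell attractant Cxcl9 was at least 48.3-fold higher. The 3 lowest genes were Npr3, the clearance receptor of natriuretic peptides, at 6.82-fold lower (5.12 to 9.23), the linker histone Hist1h1c at 3.85-fold lower (2.57 to 5.93) and the isoprenoid synthesis gene Idi1 at 5.34-fold lower (2.68 to 11.8). General capillary-like cells of IgG saline lay in clusters 1 and 5, and those of both E. coli libraries also in cluster 20, led by Gbp4, Iigp1, Gbp7 and Gbp2. Without cluster 20 the interferon median was 1.14, and within cluster 1 alone 0.73.

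Of the endothelial activation list in general capillary-like cells, 6 of 14 measured members were at least 2-fold higher and 0 lower, with a median of 0.77 (0.57 to 1.10, percentile 100), including the leukocyte adhesion molecule Sele (2.27) and Apln (1.91). The junction and identity list had a median of -0.20 (-0.30 to -0.14, percentile 3.06), with Klf4, a flow-sensitive transcription factor, at -1.26 and the tight junction gene Cldn5 at -0.59. Medians were 0.61 (0.26 to 0.71, percentile 100) for STAT3 targets, 0.34 (0.11 to 0.63, percentile 99.9) for NF-kB targets, 1.30 (1.06 to 1.56, percentile 100) for chemokines, 0.71 (0.43 to 1.06, percentile 100) for the acute phase list, 0.17 (-0.02 to 0.30, percentile 98.9) for pro-apoptotic genes and -0.25 (-0.32 to -0.17, percentile 0.860) for immediate-early genes. Within cluster 1 alone, the NF-kB and activation medians were -0.0148 and -0.006. In large vessel-like cells the interferon, MHC class I and MHC class II medians were 1.71 (1.41 to 1.95), 0.97 (0.89 to 1.16) and 2.13 (1.75 to 2.36), with 5 of 7 class II members open to free RNA. In aerocyte-like cells, the thin capillary cells of gas exchange, the interferon and MHC class I medians were 1.56 (1.34 to 1.75) and 0.90 (0.81 to 1.04), with Irf7 at 2.81. For large vessel-like and aerocyte-like cells in turn, other medians were 0.11 and 0.09 for STAT3 targets, 0.41 and 0.50 for NF-kB targets, 0.59 and 1.79 for chemokines, 1.75 and 1.15 for the acute phase list, and -0.46 and -0.66 for immediate-early genes.

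In fibroblast-like cells the median log2 ratio of all measured genes was -0.12, and values in this paragraph are given relative to it unless stated. The serum amyloid gene Saa3 had 27996 against 67.6 CPM and a relative log2 ratio of 8.62, Lcn2 had 5142 against 41.2 CPM and 6.77, and Saa1, with 0 UMIs in IgG saline, was at least 387-fold higher before the shift. Of the chemokine list, 14 of 15 measured members were at least 2-fold higher and 0 lower before the shift. Its median was 2.69 (2.44 to 2.94, percentile 100) before the shift and 2.81 relative to it. Members included Cxcl9 (5.92), Cxcl5 (4.79) and the monocyte attractant Ccl2 (3.61). Of the interferon list, 21 of 23 measured members were at least 2-fold higher and 0 lower before the shift, with a relative median of 2.18. Relative medians were 1.99 for the acute phase list, 1.49 for MHC class I, 1.20 for NF-kB targets, 0.61 for STAT3 targets and 1.18 for the unfolded protein response. Matrix genes had a relative median of 0.28, with Timp1, an inhibitor of matrix proteases, at 4.01 and the collagen gene Col3a1 at 1.05. Repair growth factors had -0.32, with Ctgf at -1.16, and immediate-early genes -0.51, with Atf3 at -2.01. The 3 lowest genes were C1qa, a complement gene of macrophages (at least 53.7-fold lower), Thbs4 (at least 48.1-fold lower) and Angptl1, with 1 UMI in IgG E. coli, at 119.8-fold lower (21.2 to 4762), all before the shift. C1qa is also among the top 10 genes of monocyte- or macrophage-like cluster 26, and material from such cells was not ruled out. Fibroblast-like cells of IgG saline lay mostly in clusters 16 and 25, and those of both E. coli libraries mostly in cluster 11, led by Saa1, Timp1 and Cxcl14. Cluster 16 held 156, 0 and 0 cells of IgG saline, IgG E. coli and anti-LIF E. coli, and cluster 11 held 16, 107 and 65. Values of this class against IgG saline therefore carry that mix, and a change within the same cells cannot be told apart from it.

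In neutrophil-like cells the median of all measured genes was 0.54, and values are again relative to it unless stated. Il1a, an alarm cytokine, had 3025 against 4.24 CPM and a relative log2 ratio of 7.20, the macrophage attractant Ccl3 had 12411 against 89.1 CPM and 6.43, and Cxcl10, with 0 UMIs in IgG saline, was at least 320.0-fold higher before the shift. The 3 lowest genes were the granule protein Ngp (-5.78), the neutrophil surface marker Ly6g (-5.35) and Retnlg (-5.34). Of the chemokine list, 13 of 14 measured members were at least 2-fold higher and 0 lower before the shift, with a relative median of 2.87. Relative medians were 2.24 for NF-kB targets, with Sod2 at 5.62, 2.13 for the interferon list, with Ifi47 at 3.90, and 1.999 for MHC class I. They were 0.75 for neutrophil activation, with Tnf at 4.61 and the adhesion molecule Icam1 at 4.30, 0.65 for immediate-early genes, -0.09 for STAT3 targets and -0.04 for the acute phase list. Neutrophil-like cells of IgG saline lay in cluster 14, led by Retnlg and S100a9, and those of the E. coli libraries mostly in cluster 4, led by Il1b and Il1rn, and cluster 15, led by Ccl3 and Ccl4.

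Monocyte- or interstitial macrophage-like cells had more Cxcl10 (70.5-fold higher, 43.2 to 124), more Il1rn, the interleukin-1 receptor antagonist (42.0-fold higher, 27.4 to 68.2), and more AA467197 (34.8-fold higher, 24.6 to 51.2). The class held 92 cells of cluster 13 and 14 of cluster 26 in IgG saline but 42 and 36 in IgG E. coli, so its values carry that mix; within cluster 13 the interferon median was 1.64. Retnla was at least 97.3-fold lower, the eosinophil attractant Ccl24 13.2-fold lower (8.62 to 21.3) and the lipoxygenase Alox15 at least 35.2-fold lower. Of the interferon list, 21 of 25 measured members were at least 2-fold higher and 0 lower, with a median of 1.96 (1.70 to 2.07, percentile 100), and of the chemokine list, 11 of 15 measured members were at least 2-fold higher and 1 lower, with a median of 2.49 (2.11 to 2.63, percentile 100). With classes cut from marker scores per cell the interferon median was 1.32 and with a pseudocount of 50 CPM 1.09. With thinned cells it was 1.11, over the 8 members still measured. Medians were 0.97 (0.74 to 1.14) for NF-kB targets, 0.74 (0.68 to 0.85) for MHC class I, 0.18 (0.11 to 0.30) for MHC class II, 0.47 (0.29 to 0.70) for STAT3 targets, -0.07 (-0.16 to 0.16) for the acute phase list, -0.19 (-0.28 to -0.10) for immediate-early genes and 0.78 (0.49 to 0.88) for alveolar macrophage identity, with Olr1 at 1.82. The STAT3 median was -0.11 with thinned cells, over the 9 members still measured. Over all immune cells together, the interferon median was 2.24 (2.14 to 2.35). Neutrophil-like cells made up 100 of these 770 cells in IgG saline and 213 of 469 in IgG E. coli, and alveolar macrophage-like cells 140 and 3. The pooled value therefore carries the mix of classes and does not describe the classes of fewer than 50 cells.

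The comparison of anti-LIF with IgG in E. coli asked what differed in infected lungs when LIF was blocked. The interferon median was -1.41 in neutrophil-like, -0.9997 in monocyte- or macrophage-like and -0.55 in general capillary-like cells, where 7 of 24 members were at least 2-fold lower and the median within cluster 1 was 0.0095. For monocyte- or macrophage-like cells it was -1.28 within cluster 26 but -0.0035 within cluster 13. The MHC class I median was -1.51 in neutrophil-like cells, and between -0.42 and -0.29 in the endothelial classes. Fibroblast-like cells had less Cxcl9 (96.9-fold lower, 44.3 to 265), Cxcl5 (12.5-fold lower, 8.14 to 20.2, but 24.4 against 77.7 CPM within cluster 11), Lif (9.99-fold lower, 5.57 to 19.7) and Il6 (3.69-fold lower, 3.04 to 4.50), while 5 of 14 acute phase genes were at least 2-fold higher, with a median of 0.65. From IgG to anti-LIF E. coli, Lif had 169 UMIs in 26 cells against 12 in 8, and Il6 650 in 54 against 125 in 19. The fold intervals leave out this spread between cells. General capillary-like and large vessel-like cells had more Socs3, and these and aerocyte-like cells less Cyp26b1, which codes for an enzyme that breaks down retinoic acid. In AT2-like cells the STAT3 target median was slightly below 0, -0.05 with an interval of -0.13 to 0.00291 and a percentile of 37.7. This median was -0.39 with thinned cells, over the 16 members still measured, and -0.15 over the 13 not open to free RNA. Of 20 immediate-early genes in AT2-like cells 8, Jun and Fos among them, were at least 2-fold lower.

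The 6 highest genes in AT2-like cells were the cell cycle regulator Rgcc at 3.40-fold higher (3.22 to 3.58), the antioxidant enzyme Prdx6 at 2.82-fold higher (2.73 to 2.91), the collagen VI chains Col6a2 at 3.11-fold higher (2.75 to 3.53) and Col6a1 at 2.495-fold higher (2.34 to 2.66), Scnn1a, the alpha chain of the epithelial sodium channel, at 2.79-fold higher (2.56 to 3.04), and Selenbp1 at 2.29-fold higher (2.22 to 2.35). The 6 lowest were the transcription factor genes Jun at 2.89-fold lower (2.79 to 3.002) and Fos at 2.58-fold lower (2.43 to 2.73), the noncoding RNA Meg3 at 5.06-fold lower (4.04 to 6.39), the lung chemokine Cxcl15 at 2.64-fold lower (2.60 to 2.67), the water channel Aqp3 at 3.69-fold lower (3.07 to 4.45) and Cxcl5 at 2.46-fold lower (2.33 to 2.60). The same clusters, 0 and 3, held most AT2-like cells of both libraries.

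Of the chemokine list in AT2-like cells, 0 of 16 measured members were at least 2-fold higher and 3 lower, with a median of -0.23 (-0.34 to -0.17, percentile 0.01), and Il33, an epithelial alarm cytokine, had a log2 ratio of -1.20. Of 22 measured STAT3 targets 0 were at least 2-fold higher and 0 lower, with Osmr at -0.59 and Lrg1, a secreted glycoprotein, at -0.61. The STAT3 median was -0.39 with thinned cells, where 16 of the 22 members were still measured, and -0.15 over the 13 not open to free RNA. These values therefore do not compare the same members as the main median. Medians were -0.02 (-0.07 to 0.02, percentile 71.0) for the acute phase list, with Lcn2 at 0.58, -0.11 (-0.18 to -0.06, percentile 4.10) for NF-kB targets, -0.23 (-0.33 to -0.17, percentile 0) for the interferon list, -0.20 (-0.26 to -0.15, percentile 1.26) for MHC class I and -0.22 (-0.27 to -0.17, percentile 5.20) for MHC class II. Of the immediate-early list, 0 of 20 measured members were at least 2-fold higher and 8 lower, with a median of -0.81 (-0.88 to -0.77, percentile 0). Of the unfolded protein response list no member passed 2-fold and the median was -0.33 (-0.39 to -0.27, percentile 0), with the chaperone Hspa5 at -0.71.

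Surfactant and lipid genes in AT2-like cells had a median of -0.22 (-0.24 to -0.18, percentile 0.140), with Sftpc at 0.53 and the desaturase Scd1 at -0.70. Barrier and ion transport genes had 0.04 (0.00107 to 0.12, percentile 98.5), which was -0.0053 without members open to free RNA, and Cldn18 stood at 0.45. The transitional state list had 0.06 (-0.02 to 0.15, percentile 99.4), with the cell cycle inhibitor Cdkn1a at -0.59 and the galectin Lgals3, open to free RNA, at 0.78. The AT2-like class leaves out unnamed cluster 18, which has AT2 markers, is led by Cldn4 and Sfn and held 123 cells of anti-LIF E. coli and 14 of IgG E. coli. With clusters 18 and 32 included the transitional state median was 0.30. Cell death lists were close to 0: -0.04 (-0.10 to 0.02, percentile 23.9) for pro-apoptotic genes, with Casp6 at 0.44, 0.02 (-0.04 to 0.09, percentile 87.7) for anti-apoptotic genes, with Birc2 at 0.30, and -0.02 (-0.10 to 0.09, percentile 49.6) for pyroptosis and necroptosis, with Zbp1 at -0.39. p53 targets had -0.12 (-0.18 to -0.04, percentile 0.600), proliferation genes -0.09 (-0.18 to -0.03, percentile 6.13), oxidative stress genes -0.11 (-0.15 to -0.04, percentile 8.06), with Prdx6 at 1.48, and of 18 glycolysis genes 0 were higher and 0 lower, with a median interval of -0.04 to 0.05. Repair growth factors had -0.04 (-0.13 to 0.03, percentile 21.9) and the LIF axis list 0.00324 (-0.10 to 0.04, percentile 70.6), with no member past 2-fold.

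In general capillary-like cells, 7 of 24 interferon response members were at least 2-fold lower and 0 higher, with a median of -0.55 (-0.68 to -0.49, percentile 0). Iigp1 had a log2 ratio of -1.92, Igtp -1.56, Gbp2 -1.56 and Gbp7 -1.47. Picked from the same list after its values were seen, Irf7, Ifit1 and Isg15 had 0.04, -0.30 and -0.44. Gbp4 was 4.29-fold lower (3.60 to 5.14) and Ubd, a ubiquitin-like modifier, with 1 UMI under anti-LIF, 90.8-fold lower (15.8 to 3637). Without cluster 20, which Gbp4, Iigp1, Gbp7 and Gbp2 lead, the interferon median was -0.19, and within cluster 1 alone it was 0.0095, both tried after the values were seen. Within cluster 1, Gbp4 had a log2 ratio of -1.21, Igtp -1.09, Iigp1 -0.61 and Gbp2 -0.34, and Ubd had 0 against 0 UMIs. Of the MHC class II list, 0 of 8 measured members were at least 2-fold higher and 7 lower, with a median of -1.497 (-1.68 to -1.39, percentile 0), and within cluster 1 H2-Ab1 had -1.58 and Cd74, the class II invariant chain, -2.06. The MHC class I median was -0.38 (-0.46 to -0.30, percentile 0.01), with its regulator Nlrc5 at -1.23.

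Cyp26b1 was 11.6-fold lower (9.23 to 14.8) in general capillary-like cells. Higher genes were Ankrd37 at 4.49-fold higher (3.69 to 5.50), Socs3 at 3.82-fold higher (3.21 to 4.58) and the lipoprotein lipase gene Lpl at 3.23-fold higher (2.93 to 3.57). Within cluster 1 alone, log2 ratios were -3.13 for Cyp26b1, 2.20 for Socs3, 1.54 for Lpl and 1.74 for Ankrd37. Of the immediate-early list, 4 of 20 measured members were at least 2-fold higher and 0 lower, with a median of 0.68 (0.60 to 0.72, percentile 100), including Fosb (1.40) and Fos (1.11). Socs3 belongs to this list as well as to the STAT3 targets, so its value does not tell these lists apart. Medians were 0.32 (0.16 to 0.45, percentile 100) for STAT3 targets, 0.30 (0.21 to 0.46, percentile 99.96) for NF-kB targets, 0.07 (-0.22 to 0.23, percentile 71.3) for chemokines, 0.51 (0.35 to 0.74, percentile 100) for the acute phase list and 0.05 (-0.07 to 0.18, percentile 75.7) for pro-apoptotic genes. The endothelial activation list had -0.04 (-0.24 to 0.13, percentile 36.0), with Apln at -1.74, and the junction and identity list 0.13 (0.05 to 0.17, percentile 99.1), with Klf4 at 0.65 and the VEGF receptor Kdr at -0.53.

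The large vessel-like class is not clearly distinct from general capillary-like cells: its clusters 17 and 23 scored 2.85 and 3.91 for large vessel markers but 5.30 and 4.20 for general capillary markers, and at resolution 0.8 a cluster led by Plat and Cxcl12, as cluster 17 is, was named general capillary. Large vessel-like cells had medians of -0.51 (-0.64 to -0.34) for the interferon list, -0.42 (-0.50 to -0.34) for MHC class I and -1.68 (-2.07 to -1.37) for MHC class II, the last with 5 of 7 members open to free RNA. Their other medians were 0.54 (0.45 to 0.62) for immediate-early genes, with Fosb at 2.11 and Socs3 at 1.81, 0.31 (0.17 to 0.44) for STAT3 targets, 0.11 (-0.06 to 0.25) for NF-kB targets, 0.69 (0.29 to 0.85) for chemokines and 0.81 (0.45 to 1.03) for the acute phase list. Aerocyte-like cells had -0.58 (-0.74 to -0.37) for the interferon list, with Gbp2 at -2.22, -0.29 (-0.40 to -0.22) for MHC class I, 0.54 (0.43 to 0.63) for immediate-early genes and 0.13 (0.01 to 0.36) for STAT3 targets. Their chemokine median was -0.69 (-1.08 to -0.44), their acute phase median 0.66 (0.32 to 0.87), and their NF-kB targets stood at 1 higher and 1 lower of 13 members.

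In AT1-like cells the interferon list had 2 members higher and 7 lower of 24, with a median of -0.06 (-0.18 to 0.13, percentile 51.5): Iigp1 had a log2 ratio of -3.45 and Igtp -2.17, but Gbp2 had 2.45. The chemokine median was 2.40 (1.81 to 2.68, percentile 100), but 6 of 7 members were open to free RNA, among them Ccl3 and Cxcl2, and the median was 0.98 with a pseudocount of 50 CPM and 0.17 with no minimum UMI count for a member. The acute phase median of 1.20 (0.71 to 1.58, percentile 100) likewise rested on 7 such members of 8. Medians were 0.10 (-0.06 to 0.31) for STAT3 targets, with Il4ra, a chain of the interleukin-4 receptor, at 1.75, 0.17 (-0.03 to 0.51) for NF-kB targets, -0.15 (-0.28 to 0.02) for MHC class I, 0.27 (-0.10 to 0.49) for pro-apoptotic genes and -0.25 (-0.44 to -0.10) for immediate-early genes. Clusters 9 and 10 held most AT1-like cells of both libraries, and cluster 33 was mostly from the anti-LIF library.

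Of the chemokine list in fibroblast-like cells, 0 of 15 measured members were at least 2-fold higher and 10 lower, with a median of -1.39 (-1.55 to -1.19, percentile 0). Ccl2 had a log2 ratio of -2.97, Cxcl10 -2.12 and Cxcl1 -1.93. Of the acute phase list, 5 of 14 measured members were at least 2-fold higher and 0 lower, with a median of 0.65 (0.52 to 0.83, percentile 100), including Saa2 (2.04), Hp (1.74) and Saa1 (1.35). Of the NF-kB targets, 1 of 17 measured members were at least 2-fold higher and 5 lower, with a median of -0.47 (-0.69 to -0.33, percentile 0) and Ier3 at -1.65. The interferon median was -0.04 (-0.19 to 0.07, percentile 38.3), with Iigp1 at -1.97 and Igtp at -1.80. Matrix genes had -0.20 (-0.24 to -0.06, percentile 3.36), with the fibronectin gene Fn1 at -1.36 and Dcn at 1.22.

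The 3 highest genes in fibroblast-like cells were Aldh1a3, with 3 UMIs in IgG E. coli, at 51.7-fold higher (17.2 to 255), Adh7, with 3, at 30.1-fold higher (9.84 to 149.7), and Aldh1a2 at 17.2-fold higher (7.51 to 48.3). Within cluster 11 alone these differences were smaller or absent: Adh7 had 18.3 against 2.18 CPM, Aldh1a3 3 against 2 UMIs and Aldh1a2 0 against 0. Aldh1a2 is also among the top 10 genes of mesothelial-like cluster 31, and material from such cells was not ruled out. Cluster 11 alone gave -5.13 for Cxcl9, -1.35 for Cxcl5 and a chemokine median of -1.16. Other medians in fibroblast-like cells were -0.49 (-0.57 to -0.35) for MHC class I, -0.37 (-0.44 to -0.23) for the unfolded protein response, -0.36 (-0.45 to -0.29) for immediate-early genes, -0.08 (-0.25 to 0.06) for STAT3 targets and -0.14 (-0.34 to 0.04) for repair growth factors, with Cyr61 at -2.41.

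**Figure D2:**
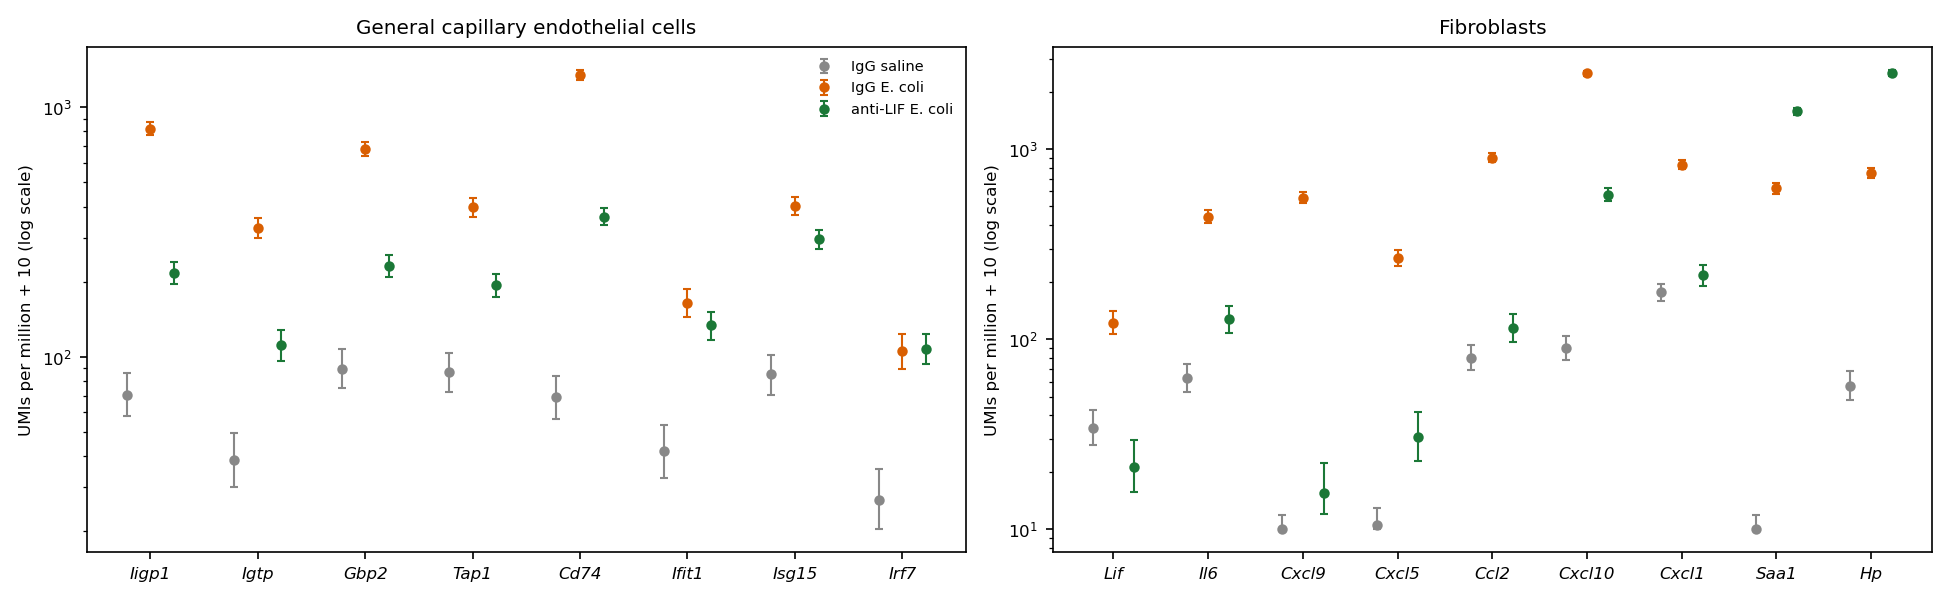
CPM plus 10, on a log axis, for 8 genes in general capillary-like cells (left) and 9 in fibroblast-like cells (right) of the 3 libraries, with 95% Poisson intervals (counting error only); the genes were chosen after their values were seen. Iigp1, Gbp2 and Cd74 lie lower with anti-LIF while Irf7 does not (log2 ratio 0.04), and in fibroblast-like cells Lif and Cxcl9 lie lower while Saa1 and Hp lie higher.

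In neutrophil-like cells, 12 of 23 interferon members were at least 2-fold lower and 0 higher, with a median of -1.41 (-1.51 to -1.07, percentile 0), and of the MHC class I list, 0 of 14 measured members were at least 2-fold higher and 12 lower, with a median of -1.51 (-1.59 to -1.32, percentile 0). Cluster 4 held 242 cells of anti-LIF and 108 of IgG E. coli and cluster 15 held 76 and 82, and the interferon median was -0.94 within cluster 4 and -1.21 within cluster 15. Ifi47, an interferon-induced GTPase, was 7.71-fold lower (6.11 to 9.81), Gbp2 had a log2 ratio of -2.41 and Nlrc5 -2.40. Higher genes were Ngp at 26.9-fold higher (11.3 to 83.7), the chitinase-like gene Chil3 at 5.88-fold higher (5.32 to 6.52) and Retnlg at 3.88-fold higher (3.60 to 4.19). Cyp26b1, with 0 UMIs under anti-LIF, was at least 40.8-fold lower and Epas1 9.55-fold lower (6.45 to 14.6); both are known as endothelial genes, and at least 3 UMIs of capillary markers were present in 13.6% of neutrophil-like cells of IgG E. coli, 2.25% of anti-LIF E. coli and 3% of IgG saline. Medians were -0.10 (-0.15 to 0.02) for neutrophil activation, with Mmp8 at 1.67, -0.01 (-0.06 to 0.06) for NF-kB targets, -0.46 (-0.52 to -0.25) for chemokines, 0.49 (0.40 to 0.60) for the acute phase list (but -0.32 within cluster 15), 0.16 (0.08 to 0.26) for STAT3 targets and 0.25 (0.17 to 0.32) for immediate-early genes.

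In monocyte- or interstitial macrophage-like cells, 12 of 25 interferon members were at least 2-fold lower and 0 higher, with a median of -0.9997 (-1.11 to -0.77, percentile 0). Within cluster 26, led by C1qb and C1qa, it was -1.28 (37 and 36 cells), but within cluster 13, led by Plac8, -0.0035 (33 and 42 cells). The median of the class was -0.41 with classes cut from marker scores per cell, -0.61 with each cell weighted alike and -0.61 with a pseudocount of 50 CPM. Cxcl10 was 6.65-fold lower (5.64 to 7.88), Gbp2 6.99-fold lower (5.30 to 9.38) and the scavenger receptor gene Marco, with 1 UMI under anti-LIF, 74.5-fold lower (13.1 to 2971). Marco is also among the top genes of alveolar macrophage-like clusters 19 and 30. That class had too few cells in IgG E. coli to enter the mark of free RNA. Higher genes were the chemokines Ccl17 at 7.36-fold higher (4.86 to 11.5) and Cxcl1 at 4.48-fold higher (3.16 to 6.48), and Prtn3, a granule protease, at 6.03-fold higher (3.19 to 12.4). Ccl17 is also among the top 10 genes of dendritic-like cluster 27 and alveolar macrophage-like cluster 30. Dendritic-like cells of anti-LIF E. coli, with 14 cells, did not enter the mark of free RNA, so material from them was not ruled out. Medians were -0.55 (-0.62 to -0.47) for MHC class I, -0.60 (-0.68 to -0.43) for MHC class II, -0.34 (-0.41 to -0.23) for chemokines, -0.06 (-0.18 to 0.04) for NF-kB targets, -0.11 (-0.27 to 0.03) for the acute phase list, with Nos2, the inducible nitric oxide synthase, at -1.75, 0.24 (0.09 to 0.36) for immediate-early genes and -0.12 (-0.27 to 0.22) for alveolar macrophage identity. The STAT3 median was -0.14 (-0.19 to -0.02), and 0.0489 with thinned cells, over the 9 members still measured. Over all immune cells together the interferon median was -0.78 (-0.91 to -0.66), a value that also carries the mix of classes.

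**Figure D3:**
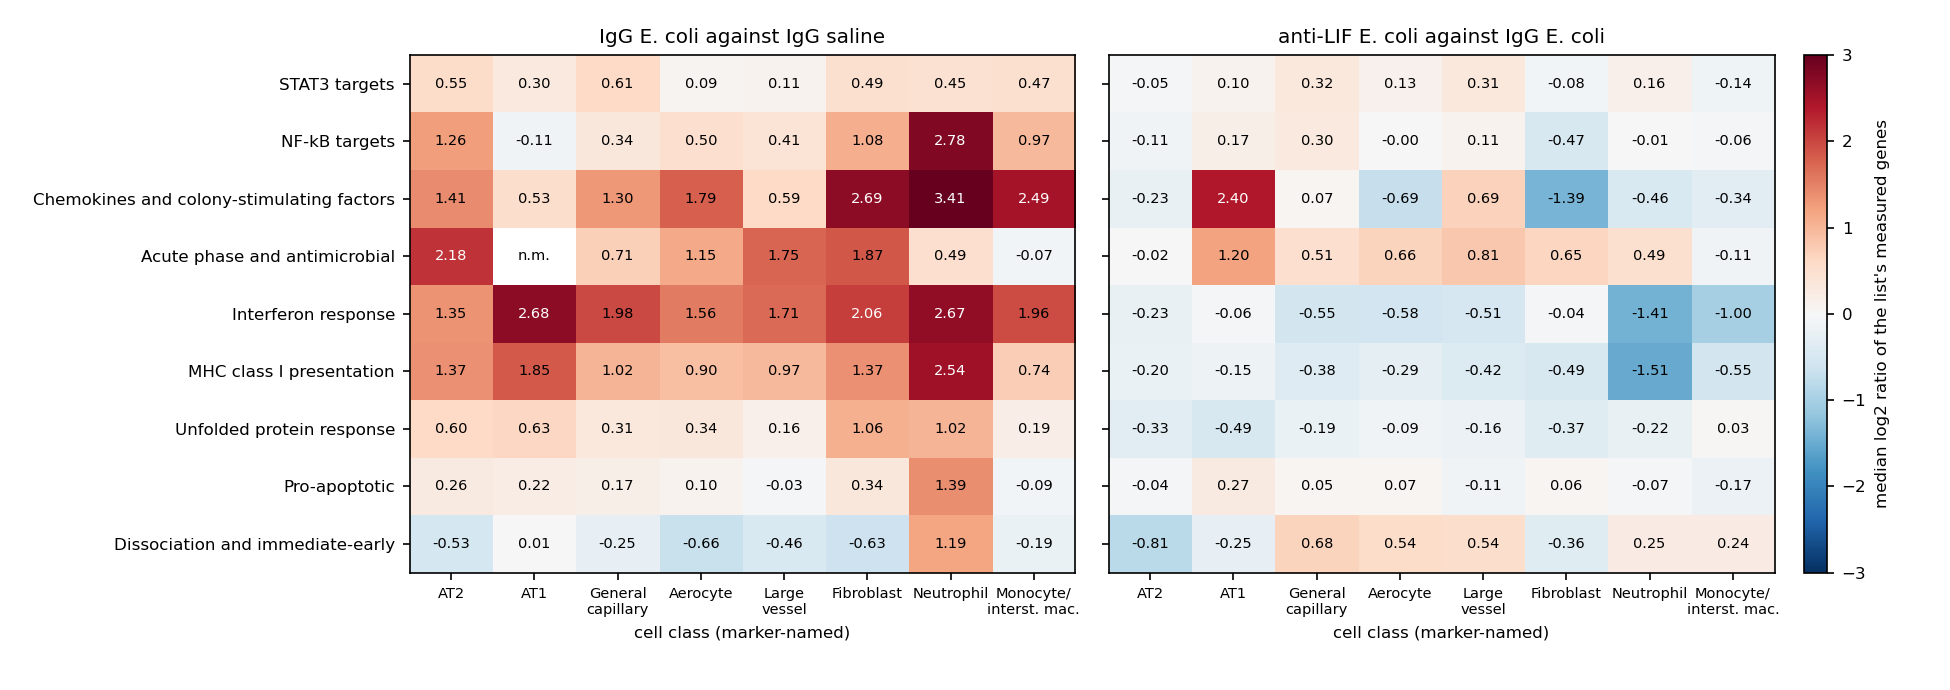
Median log2 ratio of the measured genes of 9 fixed lists (vertical) in 8 cell classes (horizontal), for IgG E. coli against IgG saline (left) and anti-LIF against IgG in E. coli (right), before any all-gene shift is taken off; n.m. marks lists with fewer than 5 measured genes. Interferon medians lie between 1.35 and 2.68 on the left and between -1.41 and -0.04 on the right.

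Set against IgG saline, the anti-LIF E. coli library had lower interferon medians than the IgG E. coli library in the classes given here, but a higher acute phase median in fibroblast-like cells. The interferon median was 0.60 (0.58 to 0.74) in AT2-like cells, 1.29 (1.11 to 1.45) in general capillary-like cells, 1.56 (1.45 to 1.74) in fibroblast-like cells and 0.81 (0.65 to 1.04) in monocyte- or macrophage-like cells, beside 1.35, 1.98, 2.06 and 1.96 for IgG E. coli against the same saline library, all before any all-gene shift is taken off. The acute phase median was 1.40 (1.33 to 1.47) in AT2-like cells and 2.78 (2.503 to 3.001) in fibroblast-like cells, beside 2.18 and 1.87, and the chemokine median 1.21 (1.13 to 1.30) and 1.60 (1.38 to 1.84), beside 1.41 and 2.69. The MHC class II median in general capillary-like cells was 0.61 (0.41 to 0.80), beside 2.17. The measured members of a list differ between comparisons, and the direct comparison of anti-LIF with IgG in E. coli did not show each of these gaps: its median was -0.02 (-0.07 to 0.02) for the acute phase list in AT2-like cells and -0.04 (-0.19 to 0.07) for the interferon list in fibroblast-like cells. Both comparisons use the same saline library, so their values share its counting error.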

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

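Tests of scaling, of Ifng in natural killer-like cells, of the acute phase list and of shared handling were chosen after the results they bear on were seen, and the subsets of neutrophil-like, monocyte- or macrophage-like, fibroblast-like, general capillary-like and aerocyte-like cells were picked after the first values. With 1 library per group, anti-LIF treatment, the mice pooled, the dose that reached each lung and the library itself cannot be told apart in any of these patterns.

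Interferon medians with anti-LIF were -1.41 in neutrophil-like, -0.9997 in monocyte- or macrophage-like and -0.51 to -0.58 in endothelial classes, with 12 of 23 members at least 2-fold lower in the first, but -0.23, -0.06 and -0.04 in AT2-like, AT1-like and fibroblast-like cells. Scaling by the class total moves every gene alike and does not account for it, since the lowest median of all measured genes in those 5 classes was -0.0589, and the neutrophil median stayed at -1.32 without cells that held 3 or more UMIs of capillary markers. A different mix of clusters is argued against by medians of -0.94 or lower within neutrophil clusters 4 and 15 and -0.53 within aerocyte cluster 6. For general capillary-like cells a different mix of clusters stays open: the median within cluster 1 was 0.0095, but 3 members of the list lead cluster 20, so the clusters were partly built from these genes, and the monocyte or macrophage median was -0.0035 in cluster 13 but -1.28 in cluster 26. A lower supply of interferon gamma may contribute, as Ifng CPM in natural killer-like cells stood at 0.344 (0.191 to 0.590) times that of IgG E. coli, but 23 and 28 cells are too few to decide and Ifng in T-like cells was similar, at 80.7 (49.9 to 123) against 87.6 (59.9 to 124) CPM.

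The chemokine list median differed in sign between classes with anti-LIF, a difference that was not tested: it was -1.39 in fibroblast-like and -0.69 in aerocyte-like cells, but 2.40 in AT1-like and 0.69 in large vessel-like cells. The AT1-like median, over 7 measured members, was 0.17 with no UMI minimum, so its size depends on which members are measured. The AT1-like and aerocyte-like values rest mostly on members open to free RNA, and the large vessel-like value on 5 members. For fibroblast-like cells, a different mix of clusters is argued against by a median of -1.16 within cluster 11, and a weaker response of every inflammatory gene by the acute phase median of 0.65 (0.52 to 0.83). The decrease was not confined to chemokines: NF-kB targets, MHC class I, unfolded protein response and immediate-early genes also had medians below 0 in fibroblast-like cells. An effect of LIF blockade on some fibroblast genes and not others could explain this and was not tested apart from the library.

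The immediate-early list median also differed in sign with anti-LIF, again not tested as a difference: it was -0.81 in AT2-like cells (8 of 20 members at least 2-fold lower), but 0.68 in general capillary-like (4 of 20 at least 2-fold higher), 0.54 in aerocyte-like and 0.54 in large vessel-like cells. The capillary median less the AT2 median was 1.60 with cells thinned to 1000 UMIs and 1.62 without members open to free RNA, so neither depth nor free RNA accounts for the gap. One handling or dissociation difference that shifts all cells one way is argued against by the compared classes outside the pattern: the median was 0.24 (0.09 to 0.36) in monocyte- or macrophage-like cells but -0.36 (-0.45 to -0.29) in fibroblast-like cells. A handling difference that acts on cell types in opposite ways might still be at work, and LIF blockade was not tested apart from the library.

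Signals also lay in unnamed clusters, which the main comparisons leave out; clusters 18 and 32 entered only an alternative for AT2-like cells. Unnamed cluster 18, with AT2 markers and led by Cldn4, Sprr1a, Sfn and Krt8, held 0.390% (0.178 to 0.738%) of kept cells in IgG saline, 0.880% (0.482 to 1.47%) in IgG E. coli and 4.80% (4.01 to 5.71%) in anti-LIF E. coli. Cluster 32, with AT2 markers and led by cell cycle genes such as Top2a and Cdk1, held 0.130% (0.0268 to 0.379%), 1.13% (0.672 to 1.78%) and 0.664% (0.387 to 1.06%). Cluster 7, shallow cells led by hemoglobin genes and the platelet genes Ppbp and Itga2b, with capillary markers as well, held 3.20% (2.52 to 4.01%), 3.39% (2.56 to 4.41%) and 4.84% (4.04 to 5.75%). These shares carry the sort and the pooling, and the differences were not tested.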

How the results depend on the processing

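The subsets by cluster, the AT2-like cells with unnamed clusters 18 and 32 and the neutrophil subset were tried after the values were seen; the other settings were fixed before the data were examined. Of 2187 alternative values of 163 list medians, 1746 lay within the counting interval of the reported value, 434 lay outside it with the same sign or no call, and 7 reversed. For single genes the numbers were 648, 78 and 2 of 728, and for class shares 233, 37 and 0 of 270. Alternatives that left a list under 5 measured members or a class under 50 cells (20 for a subset) gave no value. Because of its pseudocount each log2 ratio understates weak genes.

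The acute phase median of AT2-like cells after E. coli (2.18) was 2.58 and 1.65 with pseudocounts of 1 and 50 CPM and 1.12 with no UMI minimum. It was 1.83 with doublets kept, 2.14 at 10% mitochondrial UMIs, 2.12 with classes from marker scores, 2.24 with equal weight per cell, 2.44 with thinned cells, 1.80 without members open to free RNA and 2.12 with clusters 18 and 32. The interferon median of general capillary-like cells after E. coli (1.98) was 2.34 and 1.35 with those pseudocounts, 2.21 from 1000 UMIs per cell, 1.14 without cluster 20 and 0.73 in cluster 1. The chemokine median of fibroblast-like cells after E. coli (2.69) was 3.89 and 2.16 with those pseudocounts, 3.49 with a minimum of 50 UMIs, 2.23 with none and 3.66 with thinned cells. These 3 medians kept their sign under each alternative tried, 14 for the acute phase, 15 for the interferon and 13 for the chemokine list. A pseudocount scales ratios by construction, and a UMI minimum, a free RNA filter or thinning alters the members. Otherwise the cause was not tested.

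With anti-LIF, the general capillary interferon median (-0.55) was -0.44 with a pseudocount of 50 CPM, -0.49 with equal weight per cell and -0.19 without cluster 20, and turned to 0.0095 in cluster 1. The fibroblast chemokine median (-1.39) was -1.03 with that pseudocount, -1.16 with no minimum, -1.70 without members open to free RNA and -1.16 in cluster 11. The STAT3 median of AT2-like cells (-0.05) was -0.39 with thinned cells, over the 16 members still measured, and -0.15 over the 13 not open to free RNA. Values reversed in cluster 1 after E. coli for NF-kB targets (-0.0148) and endothelial activation (-0.006). With thinned cells they reversed for STAT3 targets of monocyte- or macrophage-like cells (-0.11 after E. coli and 0.0489 with anti-LIF, each over 9 members). They also reversed for the acute phase list of neutrophil-like cells with anti-LIF in cluster 15 (-0.32), for the AT2 barrier list with anti-LIF without members open to free RNA (-0.0053), and for Lifr in neutrophil-like cells with doublets kept (-0.24 after E. coli and 0.25 with anti-LIF). The cause was not tested. The sign held under 14 of 15 alternatives for the capillary interferon median (-0.61 to 0.0095) and 14 of 14 for the fibroblast chemokine median (-1.70 to -1.03). The AT2 STAT3 median also stayed below 0 under 14 of 14 (-0.39 to -0.0131). Its counting interval spanned 0, though, and the median of all measured genes in that comparison was -0.0127. The alternatives reuse the same counts, so the shared sign does not show a difference for this list.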

Other observations

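All values in this part were picked after they were seen. Cyp26b1 stood at 982, 479 and 50.5 (33.3 to 73.5) CPM in large vessel-like cells of IgG saline, IgG E. coli and anti-LIF E. coli, at 86.5, 45.8 and 6.13 (1.99 to 14.3) CPM in aerocyte-like cells, and at or below 1 CPM in AT2-like cells. Socs3 stood at 125, 107 and 402 (350.4 to 460.0) CPM in large vessel-like cells and 74.6, 98.2 and 136 (112 to 164) CPM in aerocyte-like cells, but at 49.7, 90.1 and 70.1 CPM in AT2-like cells.

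Ifng, interferon gamma, stood at 159 (111 to 219.7), 429 (327 to 552) and 147 (87.3 to 233) CPM in natural killer-like cells (60, 23 and 28 cells) and at 4.03 (1.10 to 10.3), 87.6 (59.9 to 124) and 80.7 (49.9 to 123) CPM in T-like cells. Club-like cells numbered 10, 7 and 97, and type 2 innate lymphoid-like cells 30, 1 and 2, and neither class was compared. The club-like cells had median depths of 12832, 14990 and 1223 UMIs, so most of the 97 were shallow.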
